A study of Homo sapiens with 8 samples.

How the data were processed

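Total RNA was sequenced from 8 cultures of 143BTK- cells, a human osteosarcoma line that lacks thymidine kinase. Per the labels, the cells grew in glucose-free medium with 10 mM galactose and 5% dialysed serum, a condition in which cells depend on mitochondrial respiration for energy. They were transfected at the start and again at 48 h with 80 pmol of a synthetic mimic of hsa-miR-101-3p or of a negative control mimic, and were harvested at 120 h. The labels describe 4 separate transfection experiments, and each group has 4 libraries numbered 1 to 4. Libraries were made after ribosomal RNA removal with the Ribo-zero Gold chemistry, per the labels.

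The deposited values are whole-number read counts per gene, not normalised, for 15982 gene symbols in 8 libraries. Between 15977 and 15982 of these genes had a count above 0 in each library, so the table holds almost no genes without reads. Per the submitters' processing notes, bcl2fastq 2.18.0.12, TopHat2 2.0.14, StringTie 1.2.4 and the hg38 genome were used. Which of these tools made the counts, the annotation behind the gene symbols, and whether counting used the strand are not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand therefore cannot be told apart, and values of such genes are given as uncertain. The same holds for genes with near-identical copies, such as histone genes, trypsinogens, genes of mitochondrial DNA with copies in the nucleus, and ribosomal protein genes with pseudogenes. Total counts ran from 17603054 to 20160267 per library, and all columns could be matched to a labelled sample.

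Choices of test, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with filterByExpr, TMM factors, glmQLFit without robust estimation and glmQLFTest, the group as the only term, and Benjamini-Hochberg adjustment. In the text "edgeR adjusted p" stands for this quasi-likelihood test, a gene is called at an adjusted p under 0.05, and log2 fold changes are given as miR-101 over negative control with their standard error. The filter left 15905 genes. CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD with n = 4 libraries per group.

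The 44 gene lists were tested with camera at a preset correlation of 0.01 on the same design, with Benjamini-Hochberg adjustment over the lists ("camera adjusted p"). Only lists with at least 3 tested members were used. Each list also has a count of members called over all genes and a count adjusted over the list alone. Camera with an estimated correlation between members and fry were run as alternatives. No list was called with an estimated correlation (1 of 44 at an unadjusted p under 0.05), and none by fry in its one-way form (15 of 44), so each list called below is lost in both. In its mixed form, which asks for changes in either direction, fry called 27 lists. Some of these, complex II among them, were not called by camera. Unless another form is named, a list is called or not called below by camera at the preset correlation. Shares of counts per library were compared with a two-sided exact permutation test over 70 permutations, with a Benjamini-Hochberg adjusted p beside the raw p over 5 shares, of which the share of 7 abundant non-coding RNAs was added after the data were seen.

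Sites that match the seed of miR-101-3p were searched in the 3' UTRs of GENCODE 29 (GRCh38) transcripts. Of the gene symbols in the table, 14077 matched an annotated name and 305 an older name, and 12457 had a 3' UTR, of which 12431 were tested. Each gene was put in the class of its strongest site in its longest 3' UTR, from 8mer through 7mer-m8 and 7mer-A1 to none. Mean fold changes of site classes were compared with two-sided permutation tests of 100000 resamples, and 1e-05 is the smallest p these can give. All 16384 words of 7 bases were ranked by the difference in mean fold change between genes with and without the word, divided by its standard error, with rank 1 for the strongest fall. Genes were treated as separate units in these tests although they are not independent replicates. Coordinates are GRCh38 positions from the same annotation.

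Genes were named by rule. The rule takes the 8 genes of complex II and its assembly factors and EZH2, a described miR-101 target. It takes the 10 largest rises and 10 largest falls among called genes with a symbol, at least 4 CPM on average and no overlap between groups. It also takes the 5 smallest p-values in each direction, up to 4 members with the smallest p-values of each list described, and every called member of the list of described miR-101 targets. This gave 143 genes, some of which are not reported here. A few other called members of lists are named to complete a count, and these were chosen after their values were seen.

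Same-numbered libraries were checked for pairing by the correlation, over genes, of their deviations from the group means. The numbers come from the sample titles, which do not say that a number marks a shared day. The correlations were 0.328, 0.425, 0.185 and 0.209 for replicates 1 to 4, all over 0.1. Some libraries of unlike number correlated as highly, so this does not settle whether the numbers pair the samples. The main test left the replicate number out, as fixed in advance, and the fit with it is an alternative. Values from a fit with the replicate number as a block stand beside some of the results they change, and not beside every count of list members. Replicate 1 of miR-101 correlated best with control replicate 2 (0.372) and replicate 4 of miR-101 with control replicate 3 (0.391).

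Libraries of a group were compared by chi-square over genes. Replicates 1 and 2 lay closest in both groups, with a chi-square per degree of freedom of 3.775 for miR-101 and 4.628 for the control, against 14.3 to 68.75 for the other pairs. All 8 libraries were kept as samples because the labels describe 4 separate experiments. The chi-square does not settle whether replicates 1 and 2 are separate experiments, since repeat libraries of 1 culture can also exceed counting noise. Because of this closeness, fits of replicates 1 and 2 alone, of replicates 3 and 4 alone, and of 3 against 3 samples with the counts of replicates 1 and 2 summed were added after the data were seen. None of these fits held the replicate block, so they do not test calls gained with it. Camera was run in these fits at the preset correlation only, so its p-values there do not measure the spread between libraries.

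Alternatives were RLE and upper-quartile factors, library sizes without the most abundant genes, no filter, a filter of at least 1 CPM in 4 libraries, the replicate block, DESeq2 1.42.0, limma-voom, robust estimation of the spread, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. For seed sites they were the shortest 3' UTR, genes of at least 4 CPM, and comparison genes matched for 3' UTR length. The alternative that leaves counts without a gene name out of the totals was not run, since every line of the table names a gene.

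The gene tests were tested on simulated data drawn from the means and library sizes of this comparison, over 15716 genes with a known set changed. In these, edgeR recovered 17.9% of genes changed 1.5-fold, 71.6% changed 2-fold and 98.5% changed 3-fold, and 8.1% of its calls were false. With the replicate block the shares were 13.4%, 58.2% and 97.0%, with 6.7% false calls. DESeq2 recovered 37.3%, 77.6% and 100.0%, with 20.6% false calls, and limma-voom 17.9%, 67.2% and 98.5%, with 6.9% false. The simulation gave a gene the same spread in every library and held no replicate effect. In the data the biological coefficient of variation was 0.054 in replicates 1 and 2 and 0.222 in replicates 3 and 4, so these shares may not hold for the data. The ranking of words was tested on the fold changes of 12431 genes, shuffled over genes. A fall of 0.1 in log2 planted in genes with a given word came back as -0.068, and that word ranked 1 of all words. Shuffling removes any link of fold changes with 3' UTR length and base composition. The test therefore does not show how the ranking does where such a link is present. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the site search, permutation tests and figures.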

Results

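RNA-seq profiled 143BTK- osteosarcoma cells grown in galactose and transfected with a mimic of the microRNA miR-101-3p or with a negative control mimic, with 4 libraries per group harvested at 120 h. Read counts were given for 15982 genes. Total counts per library ran from 17603054 (control replicate 3) to 20160267 (miR-101 replicate 3). The comparison asks which transcripts differ in cells given miR-101-3p and, from the title of the series, whether these include genes of mitochondrial respiration and of complex II, the succinate dehydrogenase of the respiratory chain. All fold changes are miR-101 over negative control.

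With the mimic, EZH2, the histone methyltransferase of Polycomb complex 2 and a described target of miR-101, fell 1.63-fold, and 14 of 32 tested genes described as miR-101 targets fell while 4 rose. TFB2M, a factor of mitochondrial transcription, fell 2.55-fold, and 7 of the 13 mRNAs encoded by mitochondrial DNA fell while none rose. Of the 8 genes of complex II and its assembly factors, none was called by edgeR in the main fit. With the replicate number as a block 1 of them, SDHB, was called lower. Among the largest rises were the cytokine IL6 (6.82-fold) and the extracellular matrix gene CCDC80 (4.31-fold), and among the largest falls the cytokine signalling adaptor SH2B3 (3.98-fold) and the innate immune receptor TLR4 (3.00-fold). Ribosomal protein mRNAs were higher as a group, and genes with a seed match for miR-101-3p in the 3' UTR were lower as a group. Neither group was called by camera with an estimated correlation (adjusted p = 0.577 for ribosomal proteins and 0.114 for 8mer and for 7mer-m8 genes).

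In all, 1053 of 15905 tested genes were called by edgeR's quasi-likelihood test at an adjusted p under 0.05, 525 higher and 528 lower, and 215 of the higher and 132 of the lower genes changed at least 2-fold. The groups did not overlap for 1027 of the called genes, and for 15.1% of all tested genes. Chance gives 2.86% if all 8 libraries are independent, and a larger share if replicates 1 and 2 are not separate experiments. With the replicate number as a block the count was 1676 (883 higher and 793 lower), of which 1029 were also called without it, and DESeq2 called 1714. Replicates 1 and 2 lay close together within each group and carried much of the evidence, and the data do not settle whether they are separate experiments. Replicates 1 and 2 alone gave 5126 calls, replicates 3 and 4 alone gave 6, all higher. In replicates 3 and 4, edgeR had 693 higher and 565 lower at an unadjusted p under 0.05, DESeq2 called 119 and 46 and limma-voom 7 and 0. Summing the counts of replicates 1 and 2 to 1 sample per group left 173 calls. Whether replicates 1 and 2 differ from replicates 3 and 4 was not tested for any gene or list below. Of the 5112 genes called in replicates 1 and 2 that were tested in replicates 3 and 4, 91.7% changed in the same direction there. Without miR-101 replicate 1, 2 or 3 the count was 488, 489 or 684, and without control replicate 1 or 2 it was 615 or 564. Of the 91 called genes that the naming rule took, 45 kept the call in each of the 8 fits that left out 1 library, and 33 kept it with replicates 1 and 2 summed.

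**Figure D1:**
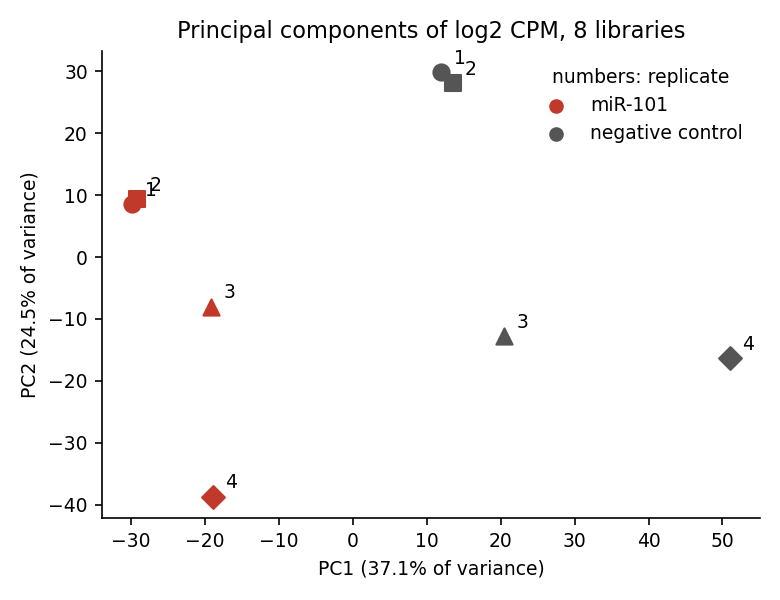
Principal components of log2 CPM for the 8 libraries, with PC1 (37.1% of the variance) on the x axis and PC2 (24.5%) on the y axis, colours for the groups and symbol shapes for the replicate number. The miR-101 libraries lie between -29.8 and -18.9 on PC1 and the control libraries between 12 and 51, and replicates 1 and 2 of each group lie side by side.

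Complex II was measured through its 4 subunits and 4 assembly factors, and none of the 8 genes was called by edgeR over all genes (2 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0). The nearest was SDHB, the iron-sulfur subunit (GRCh38 chromosome 1, 17018722 to 17054170), at 105.2 ± 7.18 CPM with miR-101 and 133.6 ± 7.38 CPM in the control (SD, n = 4 each), a log2 fold change of -0.35 ± 0.094 with an edgeR adjusted p of 0.0528. SDHB was lower in 4 of 4 same-numbered pairs and its groups did not overlap. It was the 1 gene of the 8 called when adjusted over the list alone. Its adjusted p was 0.037 in edgeR with the replicate block and 0.00593 in DESeq2, and in edgeR 0.0453 without control replicate 3 and 0.034 without control replicate 4. With replicates 1 and 2 summed it was 0.258. Its log2 fold change was -0.35 in replicates 1 and 2 and -0.35 in replicates 3 and 4 (edgeR adjusted p = 0.000149 and 0.773). SDHA, the flavoprotein subunit that binds succinate, stood at 53.1 ± 5.56 against 60.6 ± 6.39 CPM (log2 fold change -0.19 ± 0.115, edgeR adjusted p = 0.367). The membrane anchor subunits SDHC and SDHD had log2 fold changes of 0.15 ± 0.106 and -0.08 ± 0.10, the latter uncertain because TIMM8B overlaps it on the other strand. The assembly factors SDHAF1, SDHAF2, SDHAF3 and SDHAF4 had log2 fold changes of 0.31 ± 0.133, 0.27 ± 0.145, -0.28 ± 0.152 and -0.03 ± 0.185, with edgeR adjusted p from 0.202 (SDHAF1) to 0.949 (SDHAF4). The sign of SDHAF4 turned with the block (0.001). None of the 8 genes had a seed match for miR-101-3p in its longest 3' UTR. The list as a whole was not called by camera (median -0.054, camera adjusted p = 0.755). In its mixed form, which takes changes in either direction, fry called it (adjusted p = 0.00016). Of its members 3 had a positive and 5 a negative log2 fold change.

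**Figure D2:**
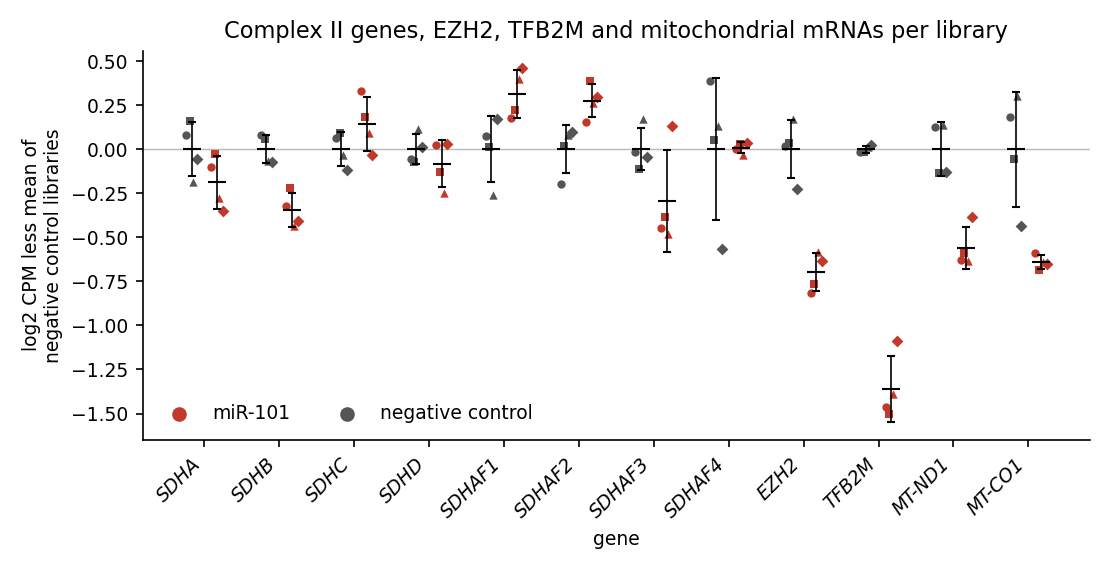
Log2 CPM of each library less the control mean (y axis) for the complex II genes, EZH2, TFB2M, MT-ND1 and MT-CO1 (x axis), with points for libraries, colours for groups and bars for the mean ± SD of 4 libraries. The miR-101 points of EZH2 and TFB2M lie below all control points, whereas those of SDHA, SDHC and SDHD overlap the control.

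Genes described as miR-101 targets were lower as a list, with a median log2 fold change of -0.50 over 32 tested members (mean -0.23), 14 lower and 4 higher over all genes and 17 lower and 4 higher adjusted over the list alone. The camera adjusted p was 5.03e-05. The adjusted p was 0.577 with an estimated correlation. EZH2 (chromosome 7, 148807383 to 148884321) stood at 28.1 ± 2.10 against 45.7 ± 5.12 CPM, a log2 fold change of -0.70 ± 0.114 with an edgeR adjusted p of 0.00561. Its 3' UTR holds an 8mer match and 2 sites in all. EED, its partner in Polycomb complex 2, fell by 0.54 (edgeR adjusted p = 0.0286), within a Polycomb list of 24 tested genes with 3 lower and 1 higher (CBX6) and a camera adjusted p of 0.537, the same counts being reached adjusted over the list alone. The largest falls were POMP, a proteasome assembly factor (log2 fold change -1.37 ± 0.126, edgeR adjusted p = 0.000542), and CDK8, the kinase of the Mediator complex (-1.14 ± 0.106, edgeR adjusted p = 0.000542). ATG4D, RAB5A, SUB1, RANBP9, TGFBR1, ATP5B, NLK, RAC1, ZEB1 and MCL1 fell by 1.05 to 0.50 on the log2 scale, of which ATG4D, RANBP9, ZEB1 and MCL1 share a locus with another gene and are uncertain. The chemokine CXCL12 (log2 fold change 2.73 ± 0.356), its receptor ACKR3 (1.46 ± 0.245), the kinase JAK2 (1.2 ± 0.112) and the transcription factor ZEB2 (0.61 ± 0.121) rose. JAK2 rose although its 3' UTR holds an 8mer match. The list's means in same-numbered pairs were -0.31, -0.31, -0.27 and 0.03, so that pair 4 did not fall. Its median was -0.58 in replicates 1 and 2 and -0.38 in replicates 3 and 4 (camera adjusted p = 6.93e-11 and 0.0412). Of the 18 called members, 9 kept the call in each fit that left out 1 library, and the other 9 lost it without miR-101 replicate 1 and, except RANBP9, without miR-101 replicate 2 (edgeR adjusted p up to 0.13, MCL1 without miR-101 replicate 1). Calls were also lost without control replicate 1 (ATG4D, NLK, ZEB1, EED, SUB1 and MCL1), control replicate 2 (NLK, ZEB1, EED, SUB1 and MCL1), miR-101 replicate 3 (EED, SUB1 and MCL1), control replicate 3 (SUB1 and MCL1) and miR-101 replicate 4 (MCL1). CBX6 lost its call in 6 of the 8 fits, all but those without miR-101 replicate 4 and control replicate 4 (edgeR adjusted p up to 0.11). EZH2 kept its call in all 8 (highest edgeR adjusted p 0.0275, without miR-101 replicate 1), but had an adjusted p of 0.565 in replicates 3 and 4 alone, where its log2 fold change was -0.59, and of 0.0809 with replicates 1 and 2 summed.

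Mitochondrial transcripts were lower as a group where they come from mitochondrial DNA. All 13 mRNAs had a negative log2 fold change (median -0.47), and 7 were called lower over all genes and 9 adjusted over the list alone. The camera adjusted p was 2.16e-07 (adjusted p = 0.577 with an estimated correlation). MT-ND2, a subunit of complex I, stood at 51.7 ± 3.67 against 79.4 ± 4.38 CPM (log2 fold change -0.62 ± 0.095, edgeR adjusted p = 0.00444), and MT-CO2, a subunit of complex IV, at 243.4 ± 18.3 against 359.6 ± 34.8 CPM (-0.56 ± 0.105, edgeR adjusted p = 0.0108). MT-CO1 fell by 0.67 and MT-ND1 by 0.56, calls that were lost in 5 and 2 of the fits that left out 1 library, without miR-101 replicates 1 and 2 in both genes and without miR-101 replicate 3 and control replicates 1 and 2 in MT-CO1 (edgeR adjusted p up to 0.0771 and 0.0545). Reads of these genes can be shared with copies in the nucleus. With replicates 1 and 2 summed MT-ND2 and MT-CO2 were not called (edgeR adjusted p = 0.0588 and 0.116). The list's means in same-numbered pairs were -0.63, -0.39, -0.65 and -0.16. Its medians in replicates 1 and 2 and in replicates 3 and 4 were -0.59 and -0.40 (camera adjusted p = 1.36e-09 and 0.000251). Genes of mitochondrial DNA took 0.218 ± 0.00833% of all counts with miR-101 and 0.317 ± 0.0574% in the control (n = 4 each), lower in 4 of 4 pairs, with a two-sided exact permutation p of 0.0286 (adjusted 0.143 over 5 shares). This p was 0.0571 without any 1 of the miR-101 libraries, where the groups still did not overlap and the exact test moves in coarse steps.

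TFB2M (chromosome 1, 246540560 to 246566324), whose product starts transcription of mitochondrial DNA, stood at 18.9 ± 2.59 against 48.1 ± 0.676 CPM (log2 fold change -1.35 ± 0.114, edgeR adjusted p = 0.000542). Its 3' UTR holds an 8mer match and 2 sites in all. It fell by 1.47 in replicates 1 and 2, and its log2 fold change was -1.25 in replicates 3 and 4 (edgeR adjusted p = 0.155). Among the 42 tested mitochondrial RNA processing and translation factors it was the 1 gene that fell, and GFM1, an elongation factor of mitochondrial translation whose locus overlaps LXN, rose by 0.41 ± 0.095 (edgeR adjusted p = 0.0281). That list was not called by camera (median 0.004, mean 0.007, camera direction lower, adjusted p = 0.997). Fry in its mixed form called it (adjusted p = 1.18e-07). OGDH, a subunit of the 2-oxoglutarate dehydrogenase of the tricarboxylic acid cycle, fell by 0.61 ± 0.111 (edgeR adjusted p = 0.00957). PDHX of the pyruvate dehydrogenase complex fell by 0.45 ± 0.095 (0.019 by edgeR, overlapping APIP) and PDP1, the phosphatase that activates that complex, rose by 0.51 ± 0.123 (0.0325 by edgeR). PDHX, GFM1 and PDP1 lost their calls without miR-101 replicate 1 or 2 or control replicate 2 (edgeR adjusted p up to 0.0973). PDHX and GFM1 also lost theirs without control replicate 1, PDHX and PDP1 without miR-101 replicate 3, GFM1 and PDP1 without miR-101 replicate 4 and PDP1 without control replicate 3, while TFB2M and OGDH kept theirs in all 8 fits. With replicates 1 and 2 summed TFB2M was called and OGDH was not (edgeR adjusted p = 0.0129 and 0.104). The list of the tricarboxylic acid cycle and pyruvate oxidation, 27 genes with these 3 calls, had a median of -0.14 and a camera adjusted p of 0.0834. Its adjusted p by fry in the mixed form was 1.82e-06.

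Nuclear genes of the respiratory chain were not called as lists over all 8 libraries. The medians were -0.082 for 34 complex I subunits (camera adjusted p = 0.0871), -0.05 for 9 complex III subunits (0.66), -0.12 for 12 complex IV subunits (0.454), -0.11 for 18 ATP synthase subunits (0.104) and -0.079 for 47 assembly factors of complexes I, III, IV and V (0.49). ATP5B, the beta subunit of ATP synthase and a described miR-101 target, was the 1 called gene of these lists, at 479.5 ± 78.9 against 755.8 ± 68.4 CPM (log2 fold change -0.66 ± 0.131, edgeR adjusted p = 0.0145), a call lost without miR-101 replicate 1 or 2 (edgeR adjusted p up to 0.0585). At an unadjusted p under 0.05 edgeR had 4 lower genes in complex I, 1 lower in complex IV, none in complex III, and 2 higher and 4 lower among the assembly factors. DESeq2 called 1 lower gene each in complexes I and IV, and limma-voom none in these 4 lists. Without miR-101 replicate 4 the lists of complex I and ATP synthase were called lower (camera adjusted p = 0.0136 and 0.00971). The tricarboxylic acid cycle list was called lower without control replicate 4 (0.0231). In replicates 1 and 2 alone the lists of complex I (median -0.14, camera adjusted p = 0.0249), ATP synthase (-0.16, 0.0169) and the tricarboxylic acid cycle (-0.17, 0.0154) were called lower. In replicates 3 and 4 their medians were -0.069, -0.054 and -0.10 (0.335, 0.316 and 0.335). Other lists of the organelle were not called: mitochondrial ribosomal proteins (80 genes, median -0.053, camera adjusted p = 0.406, and 0.0348 lower without miR-101 replicate 4), protein import and chaperones (36 genes, -0.005, 0.997), iron-sulfur cluster assembly (17 genes, 0.086, 0.748), DNA maintenance and dynamics (32 genes, -0.059, 0.564), and mitochondrial fatty acid oxidation (22 genes, -0.11, 0.117). In these lists TIMM10B rose (log2 fold change 0.44, uncertain because it overlaps ARFIP2) and TIMM17A (-0.50), the cristae protein IMMT (-0.47) and the lipid-responsive transcription factor PPARA (-0.75) fell. Glycolysis (24 genes, median -0.048, mean 0.006, camera adjusted p = 0.743) held 1 called gene, the glucose transporter SLC2A3, which rose by 1.99. That list was called lower in replicates 1 and 2 alone (median -0.17, camera adjusted p = 0.0169) and had a median of 0.11 in replicates 3 and 4 (0.18). The Leloir pathway of galactose use (8 genes, median -0.022, mean 0.015, camera direction higher, adjusted p = 0.919) held none by edgeR, DESeq2 or limma-voom (1 higher at an unadjusted p under 0.05).

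Cytosolic ribosomal protein mRNAs were higher as a list. Of 75 tested, 72 had a positive log2 fold change (median 0.31), 9 rose over all genes, 18 adjusted over the list alone and 20 in the fit with the replicate block. None fell by edgeR, DESeq2 or limma-voom, or at an unadjusted p under 0.05. The camera adjusted p was 5.89e-10 (adjusted p = 0.577 with an estimated correlation). RPS3 stood at 1549 ± 74.2 against 1156 ± 33.5 CPM (log2 fold change 0.42 ± 0.09, edgeR adjusted p = 0.0194) and RPL12 at 202.1 ± 33.1 against 139.2 ± 11.7 CPM (0.54 ± 0.127, edgeR adjusted p = 0.03). RPS3, RPL12, RPL5 and RPL11 lost their calls without miR-101 replicate 2 or 3 and without control replicate 1 or 2 (edgeR adjusted p up to 0.101), RPL12, RPL5 and RPL11 also without miR-101 replicate 4, and RPL5 and RPL11 also without miR-101 replicate 1. Reads of this family can be shared with pseudogenes, and RPL5 overlaps FAM69A on the other strand. The list's median was 0.32 in replicates 1 and 2 and 0.32 in replicates 3 and 4 (camera adjusted p = 1.15e-12 and 9.76e-08).

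Inflammatory cytokines and NF-kB targets were also higher, with a median of 0.58 over 21 tested genes, 4 higher and 1 lower over all genes, 9 and 2 adjusted over the list alone, and 8 and 3 with the block. The camera adjusted p was 7.21e-06 (adjusted p = 0.577 with an estimated correlation). IL6 (chromosome 7, 22725884 to 22732002) stood at 12.5 ± 1.97 against 1.81 ± 0.812 CPM (log2 fold change 2.77 ± 0.286, edgeR adjusted p = 0.000612), and BIRC3, an inhibitor of apoptosis induced by NF-kB, at 73.0 ± 14.5 against 20.8 ± 4.29 CPM (1.81 ± 0.183, edgeR adjusted p = 0.000612). The chemokines CXCL1 and CXCL8 rose by 1.88 and 1.86 from low levels. IL1B, the interleukin-1 beta gene, went the other way, at 1.84 ± 1.03 against 6.21 ± 1.08 CPM (log2 fold change -1.74 ± 0.327, edgeR adjusted p = 0.0112). The list's median was 0.34 in replicates 1 and 2 and 0.84 in replicates 3 and 4 (camera adjusted p = 0.00304 and 5.03e-10).

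The interferon and double-stranded RNA response had a median of 0.26 over 38 genes, 0 called by edgeR over all genes or adjusted over the list alone and 3 higher with the block (2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0), with a camera adjusted p of 0.0395 (0.00116 with the block, and adjusted p = 0.908 with an estimated correlation). Its means in same-numbered pairs were -0.09, -0.01, 0.64 and 1.2. In replicates 1 and 2 alone the median was -0.064 (camera adjusted p = 0.24) and in replicates 3 and 4 alone 0.89 (8.27e-19). These p-values take members as nearly independent, whereas their estimated correlation over all libraries was 0.753. The call was lost without miR-101 replicate 1 or 2 (camera adjusted p = 0.0899 and 0.0984) and without control replicate 3 or 4 (0.219 and 0.906). CXCL10 stood at 2.92 ± 1.05 against 1.11 ± 0.895 CPM, and EIF2AK2, the kinase PKR, whose counts are uncertain because GPATCH11 overlaps it, at 167.8 ± 19.1 against 140.6 ± 8.60 CPM, with edgeR adjusted p of 0.183 and 0.186. The hypoxia response had a median of 0.14 over 29 genes, 3 higher and none lower over all genes and 4 higher adjusted over the list alone, with a camera adjusted p of 0.0395 (adjusted p = 0.883 with an estimated correlation). ADM, the adrenomedullin gene, stood at 112.4 ± 14.4 against 43.1 ± 7.64 CPM (log2 fold change 1.39 ± 0.149, edgeR adjusted p = 0.000843), VEGFA rose by 0.92 ± 0.178 (edgeR adjusted p = 0.0123) and the collagen-modifying PLOD2 by 0.80 ± 0.156 (edgeR adjusted p = 0.0135). In replicates 1 and 2 alone ADM, VEGFA and PLOD2 rose by 1.24, 0.64 and 0.61 (edgeR adjusted p = 3.81e-24, 1.92e-11 and 6.44e-12). In replicates 3 and 4 alone edgeR called none of these genes. The hypoxia list's median was -0.14 in replicates 1 and 2 and 0.46 in replicates 3 and 4 (camera adjusted p = 0.745 and 1.06e-06). The call was lost without miR-101 replicate 3 (0.225) or control replicate 4 (0.583).

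Replication-dependent histone genes had a median log2 fold change of 0.29 over 52 tested genes, 48 of them positive, and a camera adjusted p of 0.00233 (adjusted p = 0.883 with an estimated correlation). None was called by edgeR over all genes or adjusted over the list alone, and 3 were called higher with the block (9 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0). The call was lost without miR-101 replicate 4 (camera adjusted p = 0.307). The list's means in same-numbered pairs were 0.31, 0.37, -0.03 and 0.36, so that pair 3 did not rise. The median was 0.32 in replicates 1 and 2 and 0.23 in replicates 3 and 4 (camera adjusted p = 1.58e-10 and 0.0467). HIST2H2AC stood at 415.2 ± 74.6 against 307.0 ± 13.9 CPM (edgeR adjusted p = 0.0725). Counts within this family of near-identical genes are uncertain. Histone genes took 0.776 ± 0.140% of counts with miR-101 and 0.657 ± 0.161% in the control (n = 4 each, two-sided exact permutation p = 0.343, adjusted 0.857). The difference of 0.12 percentage points was 0.0524 without miR-101 replicate 4 and 0.20 without control replicate 4.

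A list fixed as DNA methylation and histone demethylation enzymes, which also holds histone methyltransferases such as NSD1, was lower, with a median of -0.18 over 28 genes, 3 lower over all genes, 5 adjusted over the list alone and a camera adjusted p of 0.00299 (adjusted p = 0.577 with an estimated correlation). DNMT3B, a de novo DNA methyltransferase, stood at 18 ± 4.56 against 39.9 ± 15.3 CPM (log2 fold change -1.15 ± 0.276, edgeR adjusted p = 0.0325), TET2, which oxidises methylated cytosine, at 19.7 ± 2.70 against 30.1 ± 5.42 CPM (-0.61 ± 0.156, edgeR adjusted p = 0.0429), and NSD1 at 73.9 ± 10.4 against 112.6 ± 13.5 CPM (-0.61 ± 0.13, edgeR adjusted p = 0.02). DNMT3B and TET2 lost their calls without miR-101 replicate 1, 2 or 4 or control replicate 1 or 2, DNMT3B also without miR-101 replicate 3 and TET2 also without control replicate 3 (edgeR adjusted p up to 0.13). NSD1 lost its call without miR-101 replicate 3 or control replicate 2 (up to 0.0639). The median was -0.15 in replicates 1 and 2 and -0.21 in replicates 3 and 4 (camera adjusted p = 0.00304 and 0.00339). Small RNA processing and silencing genes had a median of -0.16 over 24 genes, 2 lower over all genes, 5 adjusted over the list alone and a camera adjusted p of 0.0308 (adjusted p = 0.577 with an estimated correlation). TNRC6B, a partner of Argonaute proteins, fell by 0.50 ± 0.127 and the helicase DDX6 by 0.38 ± 0.096 (edgeR adjusted p = 0.0399 and 0.0395). Both calls were lost without miR-101 replicate 1, 2 or 4 or control replicate 1, 2 or 3, and that of DDX6 also without miR-101 replicate 3 (edgeR adjusted p up to 0.122). The list's medians in replicates 1 and 2 and in 3 and 4 were -0.15 and -0.20 (camera adjusted p = 0.0267 and 0.0542). The call was lost without miR-101 replicate 2 (0.072) or control replicate 3 (0.0904).

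G1/S cell cycle genes had a median of -0.12 over 46 genes, with 4 lower over all genes, 4 lower adjusted over the list alone and a camera adjusted p of 0.0395 (adjusted p = 0.638 with an estimated correlation). UNG, the uracil-DNA glycosylase, fell by 0.92 ± 0.108 (edgeR adjusted p = 0.00131), RRM1, a ribonucleotide reductase subunit, by 0.51 ± 0.116 (0.026 by edgeR), and E2F1 and DTL by 0.45 and 0.37. UNG kept its call in all 8 fits that left out 1 library, while the other 3 genes lost theirs without miR-101 replicate 1, 2 or 3 or control replicate 1 or 2. DTL lost its call also without miR-101 replicate 4 or control replicate 3 (edgeR adjusted p up to 0.14). The list's medians in replicates 1 and 2 and in 3 and 4 were -0.15 and -0.072 (camera adjusted p = 0.00675 and 0.335). The call was lost without miR-101 replicate 1 or 2 (0.109 and 0.0911) and without control replicate 3 or 4 (0.0937 and 0.0579). G2/M genes (55 tested, median 0, mean -0.042, camera adjusted p = 0.66) held 3 genes that fell over all genes, KIF11, LMNB1 and FAM64A, the last uncertain because it overlaps PITPNM3. Adjusted over the list alone edgeR called none, against 4 higher and 7 lower at an unadjusted p under 0.05, 4 lower by DESeq2 and 3 lower by limma-voom over all genes. KIF11 and LMNB1 lost their calls in all fits that left out 1 library except that without miR-101 replicate 4, and FAM64A in all except those without control replicate 3 or 4 (edgeR adjusted p up to 0.15).

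**Figure D3:**
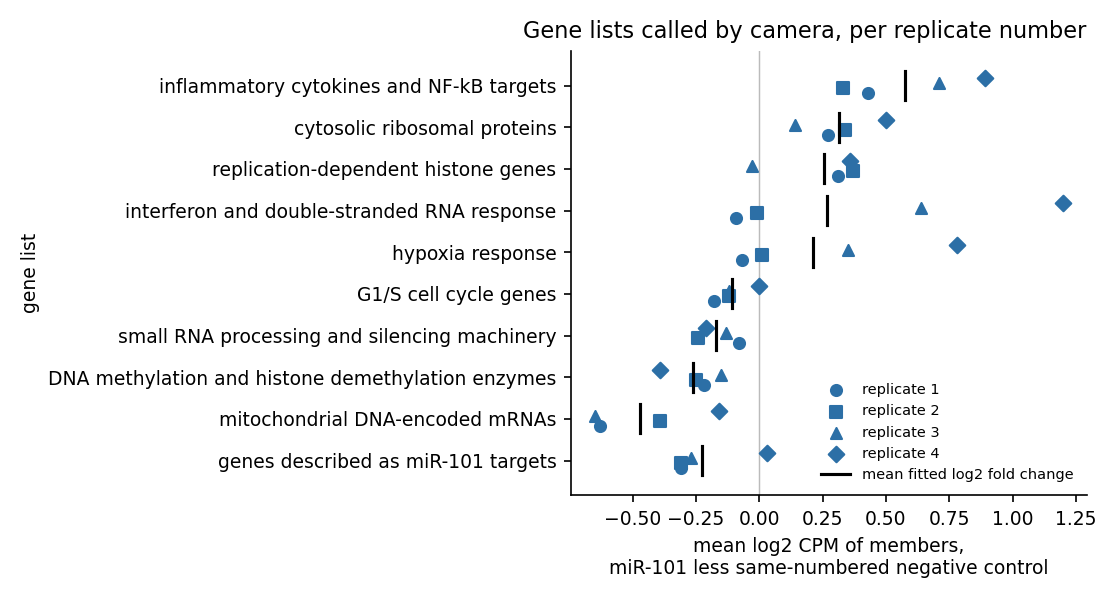
Mean log2 CPM of the members of each of the 10 called gene lists (y axis), miR-101 less the same-numbered negative control library (x axis), with 1 point per replicate number and a black line at the mean fitted log2 fold change of the list. The 4 points of ribosomal proteins lie between 0.14 and 0.50 and those of mitochondrial mRNAs between -0.65 and -0.16, whereas those of the interferon list run from -0.09 to 1.2.

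The 10 largest rises and falls were taken among called genes of at least 4 CPM on average whose groups did not overlap. Among the 10 largest rises, the transmembrane protein TMEM200C rose by 2.52 ± 0.399, the peptidase DPP4 by 2.48 ± 0.554, stomatin (STOM) by 2.15 ± 0.238 and the integrin subunit ITGA9 by 2.12 ± 0.456. The hyaluronan-binding CEMIP rose by 2.05 ± 0.478, PLXDC2 by 2.04 ± 0.199 and the adrenomedullin receptor CALCRL by 2.02 ± 0.476 on the log2 scale. CCDC80 (chromosome 3, 112596794 to 112649530) stood at 85.9 ± 2.23 against 19.9 ± 3.37 CPM (log2 fold change 2.11 ± 0.128, edgeR adjusted p = 4.12e-05). It was among the 6 genes called in replicates 3 and 4 alone (edgeR adjusted p = 0.0237). Among the 10 largest falls were SH2B3 (chromosome 12, 111405948 to 111451623), at 12 ± 3.01 against 47.8 ± 4.36 CPM (-1.99 ± 0.174, edgeR adjusted p = 0.000542), and TLR4 (chromosome 9, 117704175 to 117724730), at 26.3 ± 0.899 against 79.1 ± 11.4 CPM (-1.59 ± 0.119, edgeR adjusted p = 0.000236). The others were TMC7, IL1B, the acyltransferase GPAT3, the non-coding APCDD1L-AS1, MUM1L1, the endothelial transcription factor KLF2, the kinase subunit PIK3CG, and the trypsinogen PRSS3, which fell by 2.63 ± 0.483 and, without control replicate 4, by 1.85. SH2B3 and TLR4 hold an 8mer match in the 3' UTR. ITGA9, CEMIP and SH2B3 overlap ITGA9-AS1, MESDC2 and ATXN2 on the other strand. PRSS3 has near-identical paralogs. The counts of these genes are uncertain. The smallest p-values also took in the kinase STK25 (log2 fold change 1.88 ± 0.11, edgeR adjusted p = 4.12e-05, overlapping FARP2), the matrix gene EDIL3 (1.45 ± 0.131), the phosphodiesterase PDE7B (1.60 ± 0.151) and MRGBP (-1.24 ± 0.11), a subunit of the NuA4 histone acetyltransferase. Of the 20 largest changes 15 kept their calls in each of the 8 fits that left out 1 library. DPP4, ITGA9, CEMIP and KLF2 lost theirs without miR-101 replicate 1 or 2, DPP4 also without control replicate 1, ITGA9, CEMIP and KLF2 also without miR-101 replicate 3, and KLF2 also without miR-101 replicate 4 (edgeR adjusted p up to 0.0838). CALCRL lost its call without miR-101 replicates 1, 2 and 3 and control replicates 2 and 3 (up to 0.0886), and its log2 fold change was 2.68 without control replicate 1.

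Extracellular matrix genes moved in both directions, with 7 higher and 4 lower of 48 over all genes. Adjusted over the list alone the counts were 11 and 7. The median was 0.14 and the camera adjusted p 0.0871, and 0.0114 higher with the replicate block. With replicates 1 and 2 summed, and no block, it was 0.0742. The list was called higher in replicates 1 and 2 alone (median 0.18, camera adjusted p = 0.015) and in replicates 3 and 4 alone (0.23, 0.0182). The proteoglycan VCAN rose by 1.27 ± 0.178 (edgeR adjusted p = 0.00271), while FBN2, a fibrillin, fell by 1.08 ± 0.119 (0.000976 by edgeR, overlapping SLC27A6) and the collagenase MMP1 by 0.91 ± 0.115 (0.00175 by edgeR). LUM was higher at 2.01 ± 0.264 against 0.0815 ± 0.0894 CPM (edgeR adjusted p = 0.000612), and its fold is not given because the control level rests on few reads. The list was called higher without miR-101 replicate 3 or 4 (camera adjusted p = 0.0426 and 0.00349) and without control replicate 1 or 2 (0.0285 and 0.00915). Epithelial-mesenchymal transition regulators (24 genes, median 0.13, camera adjusted p = 0.765) held 2 higher genes, TGFB2 (log2 fold change 1.32 ± 0.182) and ZEB2, and 3 lower, ITGA5 (-0.91 ± 0.171), TGFBR1 and ZEB1, with 7 and 5 adjusted over the list alone. Osteoblast and bone matrix genes (10 genes, median 0.12, camera adjusted p = 0.225) held 1 called gene, the bone transcription factor RUNX2, which rose by 0.93, and that list was called higher in replicates 1 and 2 alone (0.0479, against 0.18 in replicates 3 and 4). Immediate early and growth factor response genes (28 genes, median -0.15, camera adjusted p = 0.0871, 0.0367 lower with the block and 0.103 with replicates 1 and 2 summed) held 3 lower genes, KLF2, SPRY4 and SPRED1, against 7 lower and 2 higher adjusted over the list alone. SPRED1 lost its call without miR-101 replicate 1 or 2, and SPRY4 in all fits that left out 1 library except those without miR-101 replicate 3 or control replicate 4 (edgeR adjusted p up to 0.115). The list was called lower in replicates 1 and 2 alone (0.0115, against 0.157 in replicates 3 and 4) and without miR-101 replicate 3 (0.027) or control replicate 4 (0.0337). YAP and TEAD targets (22 genes, median -0.19, camera adjusted p = 0.441) held 1 higher gene, TGFB2, and 2 lower, NT5E and PTPN14. Both lost their calls without miR-101 replicate 1, 2 or 4 or control replicate 2, NT5E also without miR-101 replicate 3 or control replicate 1 and PTPN14 also without control replicate 3 (edgeR adjusted p up to 0.105). The list's median was -0.32 in replicates 3 and 4 (camera adjusted p = 0.00536) and -0.003 in replicates 1 and 2 (0.678), and its direction turned without control replicate 4 (0.808).

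Lists of stress and survival genes were not called by camera over all 8 libraries. Fry in its mixed form called the BCL2 family (adjusted p = 6.6e-05), NRF2 genes (1.53e-05), p53 targets (2.22e-06) and the heat shock response (0.000292). It called none of the other lists in this paragraph. BCL2 family genes and caspases (29 genes, median -0.031, mean 0.028, camera direction higher, adjusted p = 0.997) included BIRC3, which rose, and MCL1 and APAF1, which fell by 0.50 and 0.46 and are uncertain because they overlap ADAMTSL4-AS1 and ANKS1B. MCL1 and APAF1 lost their calls in all fits that left out 1 library except that without control replicate 4 (edgeR adjusted p up to 0.13). NRF2 and antioxidant genes (27 genes, median -0.11, camera adjusted p = 0.0871) held 3 that fell, NQO1, FTL and the cystine transporter SLC7A11. Their calls were lost without miR-101 replicate 2, 3 or 4 or control replicate 1 or 2, those of FTL and SLC7A11 also without miR-101 replicate 1, that of FTL without control replicate 4 and that of SLC7A11 without control replicate 3 (edgeR adjusted p up to 0.141). The p53 targets (30 genes, median 0, mean -0.044, camera adjusted p = 0.49) held 2, CDKN1A (log2 fold change -1.13) and ZMAT3 (-1.33). The heat shock response (16 genes, median -0.015, 0.192 by camera) held 2, DNAJB1 (-0.56, uncertain because it overlaps TECR) and BAG3 (-0.71). For amino acid response and ATF4 targets (33 genes, median 0.036) the camera adjusted p was 0.722. It was 0.297 for the unfolded protein response (22 genes, 0.13). For autophagy and lysosome (44 genes, -0.026) it was 0.743, for cholesterol synthesis (24 genes, 0.16) 0.116 and for fatty acid synthesis (20 genes, -0.084) 0.398. Cholesterol synthesis was called higher without control replicate 1 or 2 (0.0259 and 0.0455) and in replicates 3 and 4 alone (median 0.38, 0.00028), and had a median of 0.004 in replicates 1 and 2 (0.863). In replicates 1 and 2 alone, camera called NRF2 and antioxidant genes (median -0.094, adjusted p = 0.0245) and fatty acid synthesis (-0.16, 0.0143) lower. Their medians in replicates 3 and 4 were -0.13 and 0.004 (0.137 and 0.967).

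Markers of other cell types were fixed to look for foreign RNA. These lists were called over all 8 libraries only with the replicate block. With replicates 1 and 2 summed they were not called (camera adjusted p = 0.101 for epithelial, 0.122 for blood and 0.147 for endothelial markers). That summed fit held no block, so it does not bear on the calls gained with it. In replicates 1 and 2 alone camera called all 3 lists (0.0116, 0.0138 and 0.00811), and in replicates 3 and 4 alone the epithelial list (0.0453, against 0.316 and 0.376). Of 15 epithelial markers 7 were tested, with a median of 0.51 and a camera adjusted p of 0.099 (0.0171 higher with the block, and 0.0237 without miR-101 replicate 4). KRT8 was higher at 117.3 ± 23.2 against 61.4 ± 12.4 CPM (edgeR adjusted p = 0.0114, overlapping KRT18). Of 18 blood cell markers 4 were tested, all with a negative log2 fold change, with a median of -0.75 and a camera adjusted p of 0.0871 (0.0114 with the block, and 0.0337 without control replicate 4). Of 12 endothelial markers 6 were tested, with a median of -0.37 and a camera adjusted p of 0.104 (0.0396 lower with the block, and 0.047 without control replicate 3). TIE1 was lower at 18.4 ± 4.83 against 45.5 ± 16.7 CPM (edgeR adjusted p = 0.02, lost in 4 of the 8 fits that left out 1 library, without miR-101 replicate 3 or 4 or control replicate 1 or 2). Ribosomal RNA genes took 0.0304 ± 0.0103% of counts with miR-101 and 0.0321 ± 0.0225% in the control (two-sided exact permutation p = 0.914, adjusted 0.914). The 50 most counted genes took 22.3 ± 2.48% and 22.0 ± 2.35% (two-sided exact permutation p = 0.771, adjusted 0.914).

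Genes with a seed match for miR-101-3p in the 3' UTR were lower than genes without one. Over 571 genes with an 8mer the mean log2 fold change lay 0.25 below that of 9477 genes without a site (difference -0.25 ± 0.022 SE, permutation p = 1e-05, the smallest 100000 resamples can give). Of the 8mer genes 73.0% had a negative log2 fold change, against 51.9%. For 1014 genes with a 7mer-m8 the difference was -0.084 ± 0.015 (permutation p = 1e-05). For 1369 genes with a 7mer-A1 it was 0.03 ± 0.012 in the other direction (permutation p = 0.0103). It was -0.002 against genes of the same 3' UTR length and -0.009 without control replicate 4. Camera over the 4 site classes gave an adjusted p of 6.27e-14 for 8mer and 0.031 for 7mer-m8 genes (adjusted p = 0.114 for both with an estimated correlation). The 8mer difference was -0.29 in replicates 1 and 2 and -0.22 in replicates 3 and 4. Among called genes with a 3' UTR, 212 of 482 lower genes (44.0%) held an 8mer or 7mer-m8, against 1585 of 12431 tested genes (12.8%; odds ratio 6.05, Fisher's exact p = 6.48e-68). Of 444 higher genes, 54 (12.2%) did (odds ratio 0.95, Fisher's exact p = 0.772). The lower genes with an 8mer include EZH2, TFB2M, POMP, CDK8, SH2B3 and TLR4.

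**Figure D4:**
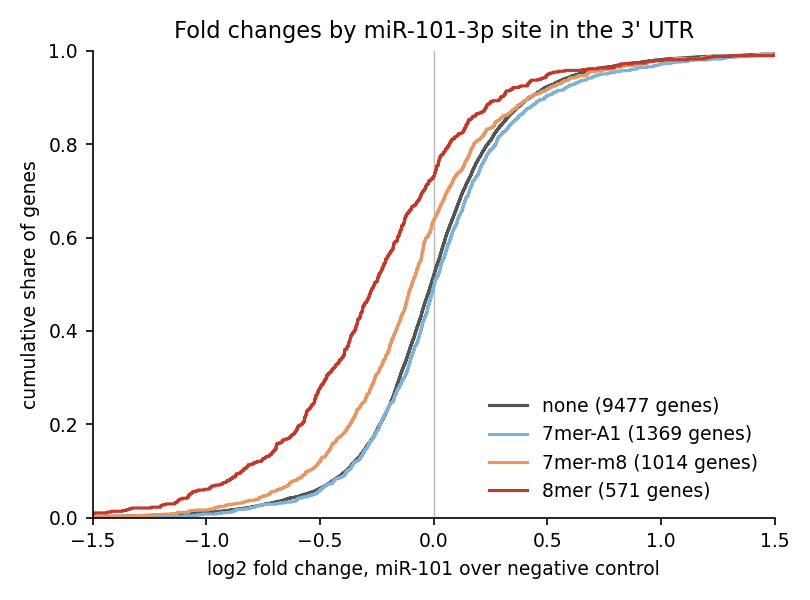
Cumulative share of genes (y axis) by log2 fold change (x axis), with a line for genes with an 8mer, a 7mer-m8, a 7mer-A1 or no seed match in the 3' UTR. The 8mer line lies to the left of the line for genes without a site (medians -0.261 and -0.012).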

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

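The tests of abundant genes, of TFB2M, of the choice of size factors and of other splits of the libraries, and the share of 7 abundant non-coding RNAs, were chosen only after the result they bear on was seen. The rank of the seed match was planned, but the limits used to read it were written after the result was seen. In 23 of 298 groups of 4 libraries, 1 library stood far from the other 3, where chance gives about 14.9 (1 in 20 groups). Of these, 9 were in control replicate 4, 7 in miR-101 replicate 4, 3 in miR-101 replicate 3, 2 in control replicate 3 and 1 each in miR-101 replicate 1 and control replicate 1. Replicates 1 and 2 of each group lie close together, and the cause was not tested.

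Control replicate 4 had the highest control value for PRSS3 (26.38 CPM, next 7.63), GPAT3 (60.7 CPM, next 35.9), HIST1H1D (176.6 CPM, next 102.3) and the share of histone genes (0.8966% of counts, next 0.588%). It had the lowest control value for PLOD2 (326.7 CPM, next 523.7), TGFBR1 (247.3 CPM, next 295.5), APAF1 (49.33 CPM, next 61.5), COX8A (114.9 CPM, next 137.1) and NLK (25.19 CPM, next 29.2). Control replicate 3 was highest for SUB1 (655.6 CPM, next 441.6) and RANBP9 (63.0 CPM, next 47.3), and control replicate 1 for PDE7B (6.922 CPM, next 4.97). Among the miR-101 libraries, replicate 4 was highest for SDHAF3 (27.95 CPM, next 19.5), PRSS3 (2.654 CPM, next 1.72), PDP1 (876.4 CPM, next 811.6), EED (31.85 CPM, next 24.7), the share of the 50 most counted genes (25.92%, next 21.3%) and the share of the 7 most counted non-coding RNAs (18.12%, next 13.1%), and lowest for ITGA9 (11.05 CPM, next 26.5). Replicate 3 was highest for MCL1 (790.3 CPM, next 668.6) and TET2 (23.79 CPM, next 18.5) and lowest for MMP1 (226.8 CPM, next 274.6), and replicate 1 was lowest for FAM64A (29.78 CPM, next 32.2).

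The number of called genes was compared with other splits of the 8 libraries. Of 35 splits, 1 gave as many calls as the 1053 of the real groups, namely the real split itself, and the highest of the others gave 30. A share of 1 in 35 is the smallest this test can give, and it speaks against chance only if the 8 libraries are exchangeable. The split with 30 calls parts replicates 1 and 2 of both groups from replicates 3 and 4, which points to a structure of the samples that goes against exchangeability. Where the numbers pair the libraries, or replicates 1 and 2 are taken as 1 sample, the splits are too few for a share under 0.05. Of the 35 splits, 8 part every same-numbered pair, and among these the highest other count by edgeR was 0. At an unadjusted p under 0.05 these other splits had 78 to 1355 genes, against 3539 for the real groups.

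Of the 13 mRNAs of mitochondrial DNA, 7 were called lower, and the list was not called with an estimated correlation (adjusted p = 0.577) or by fry (0.0664). A few abundant genes taking most of the counts is argued against by the share of counts left to genes outside the 50 most counted, whose mean log2 difference was -0.004 ± 0.032 (77.7% with miR-101 and 78% in the control). A shift of reads to the 3 nuclear copies in the table is argued against by the lower level of these copies, 22.7 ± 1.219 CPM with miR-101 and 31.98 ± 5.193 in the control. The summed CPM of mRNAs and copies had a mean log2 difference of -0.587 ± 0.135 and no overlap between groups. That sum adds little, since the mRNAs make up nearly all of it (1879 and 2860 CPM). Reads lost to copies outside the table, or left out of the counting, cannot be seen this way. A candidate explanation is the fall of TFB2M (log2 fold change -1.352), whose product starts transcription of mitochondrial DNA and whose 3' UTR matches the seed. The design gives no library with one change and without the other, so less TFB2M cannot be told apart from other effects of the mimic on these RNAs.

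Of 75 ribosomal protein mRNAs, 72 had a positive log2 fold change and 9 were called higher, and the list was not called with an estimated correlation (adjusted p = 0.577) or by fry (0.0917). Transcript length and GC content were compared in 10000 lists of the same size matched on mean expression, length and GC content. All had a lower median than 0.313 (percentile 100, largest 0.069). This argues against both only as annotated for the transcript with the longest 3' UTR, which need not be the one expressed. The match on expression was incomplete (average log2 CPM 7.79 against 8.85). Members vary together (estimated correlation 0.437), which random lists need not, so the percentile does not measure chance. A shift of reads from pseudogenes to genes is argued against by the pseudogenes in the table. Of 126 tested, 114 had a positive log2 fold change (median 0.319). The sums of gene and pseudogenes had a median log2 difference of 0.334 over 46 genes with 130 pseudogenes. Each sum holds the gene that rose, so it adds little. Reads of a gene counted at its pseudogene cannot be told apart. The list's median was 0.311 with RLE and 0.338 with upper-quartile factors, against -0.007 and 0.019 for all genes. Size factors move all genes nearly alike. The distance of the list from all genes (0.318 and 0.319) was therefore nearly fixed in advance and says little about the choice of factors. An effect of the mimic may remain, as a hypothesis found and tested on the same libraries.

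Genes with an 8mer or 7mer-m8 lay lower on average, by 0.25 and 0.084, while those with a 7mer-A1 lay 0.03 higher, and neither of the lower classes was called with an estimated correlation (adjusted p = 0.114). Length of the 3' UTR is argued against by a difference of -0.282 ± 0.03 between 8mer genes and genes of the same 3' UTR length, and base composition by the rank of the seed match, 1 of 420 words of the same bases once length and GC were removed. The word GTACTGT ranked 5 among all words of 7 bases without that step, behind 4 words rich in C. It ranked 1 in replicates 1 and 2 and 113 in replicates 3 and 4. These values go with silencing through the miR-101-3p seed. The sites and the ranking were fixed in advance, but the limits used to read the rank were written after the result was seen. Silencing stays a hypothesis here, since only RNA levels were measured.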

How the results depend on the processing

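The fits of replicates 1 and 2, of replicates 3 and 4 and of summed replicates were chosen only after the data were seen, and the others were planned. Of the 1053 called genes none changed sign in any of these fits or in those that left out 1 library. That was nearly fixed in advance, since the groups did not overlap for 1027 of them. Of the 1053, 1044 stayed called with RLE factors, 1004 with upper-quartile factors, 1052 with abundant genes left out of the library sizes, 1051 without a filter, 1029 with the replicate block, 1040 of 1047 in DESeq2 and 1011 in limma-voom. At this depth and number of libraries edgeR recovered 17.9% of genes changed 1.5-fold and 71.6% of those changed 2-fold in simulated data with the same spread in every library. Thinner sequencing was not tried. Among the named genes 2429 values were computed under alternatives, of which 2139 kept their direction and their side of the threshold, 229 lost the call, 56 gained it and 5 changed sign. These totals leave out the 3 fits by replicate. Of the 91 called genes among those named, 91 stayed called in replicates 1 and 2 only (with 40 gained), 2 in replicates 3 and 4 only and 33 with replicates 1 and 2 summed. For gene lists 621 of 704 values stayed, 36 were weaker, 20 stronger and 27 reversed, again without the 3 fits by replicate. By camera at the preset correlation, the only form run in these 3 fits, 8 of the 10 called lists stayed called in replicates 1 and 2 only (12 gained) and 8 in replicates 3 and 4 only (4 gained). With replicates 1 and 2 summed 9 stayed called, G1/S genes were lost (0.101) and cholesterol synthesis was gained (0.0275).

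With the replicate block the count was 1676 (883 higher and 793 lower), and it was 1714 in DESeq2 (840 and 874), where 20.6% of calls in simulated data were false, against 8.1% in edgeR. It was 5126 in replicates 1 and 2 only (2534 and 2592, with 20 lists called), 6 in replicates 3 and 4 only (6 and 0 by edgeR, with 693 and 565 at an unadjusted p under 0.05, 119 and 46 by DESeq2 and 7 and 0 by limma-voom), and 173 with replicates 1 and 2 summed (106 and 67). At an adjusted p under 0.01 it was 334 (169 and 165) and at an absolute log2 fold change of at least 1 it was 347 (215 and 132), both by construction. Leaving out 1 library gave 488 to 1419 calls, 258 to 670 higher and 227 to 749 lower. It was 488, 489 and 684 without miR-101 replicates 1, 2 and 3, 615 and 564 without control replicates 1 and 2, and 1419 without control replicate 4. Such fits have fewer samples, and why the count rose without control replicate 4 was not tested.

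No list was called with an estimated correlation (0, with 1 of 44 at an unadjusted p under 0.05) or by fry in its one-way form (0, with 15 of 44), while fry in its mixed form, which takes changes in either direction, called 27. Both estimate from these libraries how members vary together, which the preset correlation does not. Adjusted p with an estimated correlation was 0.577 for mitochondrial DNA-encoded mRNAs, miR-101 targets, inflammatory genes, small RNA machinery, DNA methylation and histone-modifying enzymes and ribosomal proteins, 0.638 for G1/S genes, 0.908 for interferon genes and 0.883 for hypoxia and histone genes. By fry it was 0.0664 for the first 5 of these lists, 0.0917 for ribosomal proteins, 0.117 for G1/S, 0.547 for interferon and 0.484 for hypoxia and histone genes. Upper-quartile factors gave 0.0556 for G1/S and 0.0535 for interferon genes, and the filter of at least 1 CPM gave 0.0521 for G1/S. The replicate block called extracellular matrix (0.0114), immediate early (0.0367), epithelial (0.0171), blood (0.0114) and endothelial (0.0396) lists, ended no list call and called no other list. None of these 5 lists was called without the block over all 8 libraries, or with replicates 1 and 2 summed (0.0742, 0.103, 0.101, 0.122 and 0.147). That summed fit held no block, so it does not bear on the calls gained with it. Lists near 0 changed direction without being called: mitochondrial RNA processing with upper-quartile factors (0.946), the filter of at least 1 CPM (0.949) and fry (0.946), and mitochondrial protein import with RLE factors (0.996), no filter (0.999) and the block (0.96). The cause was not tested for any of these.

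Leaving out 1 library, camera adjusted p ran from 0.0136 to 0.192 for complex I, 0.225 to 0.997 for complex III, 0.145 to 0.996 for complex IV, 0.00971 to 0.508 for ATP synthase, 0.0231 to 0.156 for the tricarboxylic acid cycle, 0.215 to 0.96 for glycolysis, 0.751 to 0.997 for the Leloir pathway, 0.0348 to 0.808 for mitochondrial ribosomal proteins, 0.521 to 0.997 for mitochondrial RNA processing and 0.324 to 0.978 for protein import. It ran from 0.00349 to 0.109 for G1/S, 0.155 to 0.924 for G2/M, 6.69e-05 to 0.906 for interferon, 0.388 to 0.99 for ATF4 targets, 0.0259 to 0.59 for cholesterol synthesis, 0.00381 to 0.583 for hypoxia, 0.808 to 0.997 for the BCL2 family, 0.504 to 0.982 for autophagy, 0.00349 to 0.545 for extracellular matrix, 0.027 to 0.251 for immediate early genes, 0.115 to 0.808 for YAP targets, 0.0101 to 0.0904 for small RNA machinery and 2.2e-07 to 0.307 for histones. For markers it ran from 0.0237 to 0.266 (epithelial), 0.0337 to 0.171 (blood) and 0.047 to 0.23 (endothelial). Complex III and IV turned without control replicate 3, glycolysis without miR-101 replicate 4 and control replicates 1 and 2, the Leloir pathway without miR-101 replicate 2 and control replicates 3 and 4, mitochondrial RNA processing without miR-101 replicates 1 and 3 and control replicate 4, protein import without miR-101 replicate 4 and control replicates 1 and 2, and G2/M and YAP targets without control replicate 4. The BCL2 family turned without miR-101 replicate 3 and control replicates 3 and 4, ATF4 targets without miR-101 replicate 3 and autophagy without miR-101 replicate 4.

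SDHAF4 changed sign with the replicate block (log2 fold change 0.001), in limma-voom (0.016) and without control replicate 1 (range -0.188 to 0.107), CD14 without control replicate 2 (-0.525 to 0.048) and UQCRB without miR-101 replicate 4 (-0.069 to 0.30), none of them called. For shares of counts, the difference of mitochondrial DNA genes ran from -0.123 to -0.0822 percentage points, with an exact permutation p of 0.0571 without any 1 miR-101 library and 0.0286 without any 1 control library. The groups did not overlap (0.2084 to 0.2286% with miR-101, 0.2471 to 0.3701% in the control). The change of p therefore reflects the coarse steps of an exact test with so few libraries. That of histone genes ran from 0.0524 (without miR-101 replicate 4) to 0.20 (without control replicate 4). That of ribosomal RNA ran from -0.00883 to 0.00612, turning without miR-101 replicates 2 and 3 and control replicates 1 and 3, and that of the 50 most counted genes from -0.993 to 1.32, turning without miR-101 replicate 4 and control replicates 2 and 4. For seed sites, the 7mer-A1 difference was -0.002 against genes of the same 3' UTR length and ran from -0.009 (without control replicate 4) to 0.077, while the 8mer difference ran from -0.308 to -0.195 and the 7mer-m8 difference from -0.109 to -0.052.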

Other observations

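The tests of agreement between replicates were chosen only after it was seen that replicates 1 and 2 lie close together, and that of the other strand was set before its result was seen.

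The called genes included some ligands together with a receptor, and 2 inhibitors of growth factor signalling. No list of such genes was fixed, and whether they are more frequent than other genes was not tested. None of those named here was called by edgeR in replicates 3 and 4 alone. CXCL12 (1.82 ± 0.315 against 0.269 ± 0.145 CPM) and its scavenging receptor ACKR3 (3.8 ± 0.917 against 1.37 ± 0.352 CPM) both rose, by 2.73 ± 0.356 and 1.46 ± 0.245 on the log2 scale (edgeR adjusted p = 0.00208 and 0.00635). ADM and CALCRL, a receptor for adrenomedullin, rose by 1.39 and 2.02. The growth factor TGFB2 rose by 1.32 ± 0.182, from 13.9 ± 2.77 to 34.9 ± 6.75 CPM (edgeR adjusted p = 0.00253), while its receptor TGFBR1, whose 3' UTR holds an 8mer match, fell by 0.79 ± 0.101 (0.00191 by edgeR). SPRED1 and SPRY4, inhibitors of growth factor signalling, fell by 0.71 and 1.03. CALCRL lost its call without miR-101 replicate 1, 2 or 3 or control replicate 2 or 3, SPRED1 without miR-101 replicate 1 or 2, and SPRY4 without miR-101 replicate 1, 2 or 4 or control replicate 1, 2 or 3 (edgeR adjusted p up to 0.115). All of these genes lie in 4 of 4 same-numbered pairs in the given direction, and the pairs were picked after their values were seen.

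A hypothesis of a common change was tested by comparing replicates 1 and 2 with replicates 3 and 4, starting from genes called in replicates 1 and 2. Changes held by replicates 3 and 4 alone could not show this way. If replicates 1 and 2 had held only changes of their own, and genes varied independently, about as many of their genes would go either way in replicates 3 and 4. Instead 91.7% of 5112 genes called in replicates 1 and 2 had the same direction there, with a median log2 fold change of 0.345 in the called direction against 0.45 in replicates 1 and 2. Genes vary together, so the share to be seen without a common change is not known. Changes held by only some replicates are not excluded. Over all 15674 genes tested in both, 73.8% had the same direction, and the correlation of fold changes across genes, which are not independent replicates, was 0.67. The smaller number of calls in replicates 3 and 4 goes with a larger spread between them (biological coefficient of variation 0.222 against 0.054). Of the called lists, 8 stayed called in replicates 1 and 2 only and 8 in replicates 3 and 4 only. Medians of some lists differed between replicates 1 and 2 and replicates 3 and 4: -0.064 and 0.893 for interferon, -0.137 and 0.455 for hypoxia, 0.004 and 0.375 for cholesterol synthesis. These differences were not tested.

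A second hypothesis was that the other strand of the miR-101 hairpin, miR-101-5p, may also silence genes in these cells. The match to its seed, GATAACT, ranked 13994 among all words of 7 bases, and genes with it had a mean log2 fold change 0.053 above that of other genes, so no fall was seen for that strand. The strand composition of the mimic was not analysed here.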
